A study of Mus musculus with 11 samples.

How the data were processed

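Total RNA from flash-frozen tumours of Th-MYCN mice was sequenced after ribosomal RNA depletion with stranded libraries, 1 library per tumour. The 11 libraries fell into 4 groups, namely vehicle (n = 3), CBL0137 (n = 3), panobinostat (n = 2) and the combination (n = 3), by the group in each label. Per the labels, the authors used STAR, SAMtools and RSEM with the mm10 assembly. Tool versions, settings and the annotation release are not given. The authors deposited TPM values (transcripts scaled to a fixed library total) for 24411 genes. Each library was checked to sum to 1000000. TPM carry no counts, so depth, counting intervals and detection limits are unknown. For 27 rows the symbol had turned into a date, and these were named by their transcript identifier. Coordinates come from the mm10 annotation.

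Genes with at least 1 TPM in at least 2 libraries were tested, which kept 15497 and left out 8914. Values were log2(TPM + 1). One limma 3.58.1 model in R 4.3.3 fitted the 4 group means over all 11 libraries (lmFit, contrasts.fit, eBayes with a trend, 7 residual degrees of freedom). The contrasts were tested, each 2-sided with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. They were each treatment against vehicle, the combination against each single drug, and the interaction. The interaction is the change after both drugs minus the sum of the changes after each. The adjusted p values measure differences against the spread between these mice. With 3 libraries against 3, an exact permutation test of a single gene can give no p below 0.1, which is why limma's pooled spread was used. Where panobinostat or another group is left with 1 library, that library is assumed to vary like the other groups.

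Of 38 gene lists fixed beforehand, 36 had at least 5 measured members and were tested by camera with its preset correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with a correlation estimated for each list. The kidney list had 4 measured members. Mitochondrially encoded genes, Trac, Trbc1, Trbc2, Ighm, Igkc, Ly6g and Ahsp are not in the table. Member counts are also given after adjustment over the list alone. Of the marker lists, T cell, fibroblast and Schwann cell ones each shared 1 member with another list. Other lists overlapped too (Ccl2, Tap1). A mean of at least 1 TPM in vehicle was reached by 5 of 17 T cell, 1 of 11 B cell, 19 of 22 macrophage, 15 of 17 endothelial and 20 of 20 fibroblast markers.

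Genes were named by a fixed rule. It takes the furthest rises and falls among called genes with a mean of at least 5 TPM in the higher group and no overlap between the libraries of the groups, which chance gives in 10% of genes for 3 against 3. It takes 8 each way against vehicle and 5 each way between treated groups, leaving out unnamed gene models, histone cluster genes and antigen receptor segments. It adds a panel of 22 genes (among them Mycn, Cdkn1a, Mdm2, Ssrp1, Supt16, Hdac1, Hdac2, H1f0, Ifit1, Isg15, Irf7, Cxcl10, H2-K1, B2m, Cd274, Th, Cd8a, Ncr1 and Mki67) and up to 4 members of each list with the lowest adjusted p. Some genes that the rule takes are not reported here. For the interaction it takes called genes, of which there were 0. Other list members, the markers of single libraries and the genes of interferon signalling were chosen after their values were seen.

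The model was tested on simulated data with the spread of these libraries and 200 changed genes per comparison. It recovered 25.4, 77.6 and 93.9% of changes of 0.5, 1 and 2 (log2) for CBL0137 against vehicle, and 16.4, 62.7 and 98.5% for panobinostat. The combination gave 16.4, 65.7 and 92.4%, and 17.9, 73.1 and 87.9% against CBL0137 and 8.96, 62.7 and 86.4% against panobinostat. The interaction gave 0, 25.4 and 84.8%. Of unchanged genes at most 0.0719% were called. Recovery at low TPM is not known.

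Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, TMM factors, quantile normalization and rescaling without small structural RNA and histone cluster genes. Others were a replicate block, no trend, array weights, only the groups compared, and leaving out each library in turn. Permutation tests in the closing part drew 100000 permutations of list members. Genes are not independent replicates, so these p concern list members within these tumours. Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and figures. Panobinostat replicate 2 and the human transgene were not analysed here.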

Results

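RNA was sequenced from spontaneous neuroblastomas of homozygous Th-MYCN mice, in which a MYCN transgene under the tyrosine hydroxylase promoter gives tumours of the sympathetic nervous system. Tumours of about 5 mm were taken 16 h after 1 dose of vehicle (n = 3 mice), CBL0137 at 40 mg/kg intravenously (n = 3), panobinostat at 5 mg/kg intraperitoneally (n = 2, replicates 1 and 3) or both drugs (n = 3). Panobinostat replicate 2 is not analysed here. Values are in TPM, transcript abundances scaled to a total of 1000000 in each of the 11 libraries. Library depth is therefore unknown, and small RNA genes may rest on few reads. Between 12856 and 14747 genes reached 1 TPM per library, and 15497 genes were tested.

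Vehicle tumours carried high TPM of sympathoadrenal genes, among them Ddc with 278 ± 29.9 TPM and Hand2 with 163 ± 20.1 TPM (SD, n = 3), and Th with 99.6 to 179 TPM. A few RNA classes took a large part of every library. Rmrp, the RNA of RNase MRP, took 8.37 to 13.8% of all TPM over the 11 libraries. Histone cluster genes took 8.87 ± 0.662% in vehicle (SD, n = 3), 8.10 ± 1.48% after CBL0137 (n = 3), 5.54 ± 0.131% after panobinostat (n = 2) and 2.95 ± 1.47% after the combination (n = 3). Since TPM are shares of a fixed total, some results that moved under other scalings are given as well.

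Several libraries carried markers of other tissues or cells. Combination replicate 2 had adrenal cortex transcripts (Star 1362 TPM, Hsd3b1 1616 TPM), and panobinostat replicate 3 had skeletal muscle transcripts (Acta1 3110 TPM). Lower muscle levels were in combination replicate 1 (Acta1 213 TPM) and CBL0137 replicate 2 (144 TPM). Vehicle replicate 2 had kidney transcripts, with Kap at 302 TPM and 8 of 11 kidney markers over 5 times the next library. CBL0137 replicate 3 and combination replicate 1 held the highest B cell transcripts, with Cd79b at 53.7 and 19.0 TPM against 0.310 to 8.92 TPM in the other libraries.

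The comparison of CBL0137 with vehicle asks what changed in these tumours after CBL0137, a curaxin that binds DNA and traps the histone chaperone FACT on chromatin. Type I interferon-stimulated genes rose in 47 of 47 measured members (47 adjusted over the list alone), with a median log2 change of 4.06, the highest of the lists tested in this comparison. Ifit3, an antiviral effector, rose from 1.63 ± 0.426 to 253 ± 169 TPM (SD, n = 3 each), and Usp18, a brake on interferon receptor signalling, from 0.443 ± 0.146 to 142 ± 78.7 TPM. Isg15, a ubiquitin-like modifier, rose from 2.59 ± 0.451 to 186 ± 110 TPM, and the chemokine Cxcl10 from 1.31 ± 0.333 to 166 ± 132 TPM. Their log2 changes were 6.41 ± 0.43, 6.50 ± 0.36, 5.56 ± 0.37 and 5.91 ± 0.48 (SE), with limma adjusted p of 8.45e-05 for the first 3 and 0.000154 for Cxcl10. Ifit1 (chromosome 19, 34640889 to 34650009 on the mm10 assembly) rose from 0.713 to 119 ± 71.1 TPM. Ifit1bl1, Iigp1 and the monocyte chemokine Ccl12 rose by 5.73, 5.68 and 5.55 on the log2 scale. The transcription factor Irf7 rose by 5.53 ± 0.41 and the DNA sensor Ifi204 by 4.61 ± 0.31. The list's median over its members was 3.52, 3.52 and 4.96 above the vehicle mean in CBL0137 replicates 1, 2 and 3. The camera adjusted p for this list was 5.20e-61, and adjusted p = 0.338 with an estimated correlation.

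Antigen presentation and cytokine genes rose beside them after CBL0137. Of the MHC class I list, 17 of 19 members rose (18 adjusted over the list alone), with a median of 2.34. Among them were B2m (chromosome 2, 122147687 to 122153082) from 107 ± 14.4 to 814 ± 514 TPM and H2-K1 with a log2 change of 2.37 ± 0.44. The peptide transporter Tap1 and the immunoproteasome subunits Psmb8 and Psmb9 rose by 3.56 ± 0.44, 3.42 ± 0.38 and 3.37 ± 0.42, and H2-T23 by 3.20 ± 0.40. Of the chemokine and cytokine list, 18 of 25 members rose (21 adjusted over the list alone, median 1.90), with Ccl2 and Ccl7, which attract monocytes, at 3.80 ± 0.34 and 3.94 ± 0.45. NF-kB target genes rose in 9 of 22 members (20 adjusted over the list alone, median 1.17), among them Bcl2a1b, Icam1 and Il6, at 2.00, 2.04 and 1.43. Camera adjusted p were 5.97e-18, 1.40e-18 and 2.23e-11 for these 3 lists, and adjusted p = 0.338 with an estimated correlation for each. Without CBL0137 replicate 3 the NF-kB median was 0.74. MHC class II genes rose in 6 of 10 members (6 adjusted over the list alone, median 1.83, camera adjusted p = 4.52e-06), with adjusted p = 0.455 with an estimated correlation. H2-Aa, H2-Ab1, H2-DMa and H2-DMb1 were among them, at 2.00, 1.96, 1.73 and 1.85. Cd274, which encodes the checkpoint ligand PD-L1, rose from 0.843 ± 0.0651 to 16.1 ± 12.5 TPM (SD, n = 3 each), and 2 of 12 checkpoint genes rose in all (3 adjusted over the list alone).

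Markers of immune and stromal cells were higher after CBL0137. Macrophage and monocyte markers rose in 13 of 22 members (18 adjusted over the list alone, median 1.52). These included Ly6c2 at 4.98 ± 0.47, Fcgr1 at 3.27 ± 0.29, the scavenger receptor Msr1 at 2.33 ± 0.25 and Fcer1g at 1.81 ± 0.25. Neutrophil markers rose in 2 of 8 members (S100a8 by 2.55 and Csf3r by 1.24, 5 adjusted over the list alone), dendritic cell markers in 3 of 10 (Irf8, Itgax and Batf3, 8 adjusted over the list alone) and fibroblast and pericyte markers in 4 of 20 (Thy1, Col6a1, Tagln and Acta2, 11 adjusted over the list alone). For these 4 lists camera gave adjusted p of 2.69e-15, 0.000459, 0.000380 and 1.79e-07, and adjusted p = 0.338 with an estimated correlation for each. Endothelial markers rose in 3 of 17 members (Egfl7, Pecam1 and Tie1 by 1.28, 1.32 and 1.58, 11 adjusted over the list alone). T cell and B cell markers each rose in 1 member, Thy1 by 1.65 of 17 and Cd22 by 1.74 of 11 (1 each adjusted over the list alone), and Cd8a was at 0.263 ± 0.169 and 1.74 ± 1.38 TPM (SD, n = 3 each, adjusted p = 0.168). The endothelial, T cell, B cell and checkpoint lists had camera adjusted p of 2.11e-07, 4.83e-05, 0.000660 and 0.00360, and adjusted p = 0.469 with an estimated correlation for each. NK cell and cytotoxic markers had a median of 0.83 with 0 of 6 members past limma's threshold (0 adjusted over the list alone), camera adjusted p = 0.0261, and adjusted p = 0.518 with an estimated correlation. That call was lost without vehicle replicate 1 (0.0615) and without CBL0137 replicate 3 (0.112), the library whose B cell median stood at 3.43 against 0.03 and 1.05 in CBL0137 replicates 1 and 2. Without that library the fibroblast, T cell, B cell, checkpoint and NK cell medians were 0.62, 0.59, 0.42, 0.24 and 0.42.

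Cdkn1a (chromosome 17, 29090979 to 29100722), the cyclin-dependent kinase inhibitor p21, rose from 4.96 ± 1.35 to 26.4 ± 18.3 TPM after CBL0137 (SD, n = 3 each), a log2 change of 2.03 ± 0.36 (SE) with a limma adjusted p of 0.0107. In the p53 target list 5 of 36 members rose and 1 fell (10 and 1 adjusted over the list alone, median 0.43), and the risen ones were Cdkn1a, Tap1, Gdf15, Pmaip1 and Ptp4a3. Mdm2, the ubiquitin ligase of p53, was at 46.1 ± 5.50 and 41.7 ± 4.93 TPM (adjusted p = 0.505). The p53 list had a camera adjusted p of 0.000654 and the immediate-early list, in which Zfp36, Atf3 and Junb rose (3 of 19, 3 adjusted over the list alone), one of 0.000585, and adjusted p = 0.469 with an estimated correlation for both. Without CBL0137 replicate 3 their medians were 0.22 each. Of the apoptosis regulators Casp8, Bak1 and Pmaip1 rose by 1.79, 1.15 and 1.29 (3 of 24, 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0673, and 0.0376 without CBL0137 replicate 2).

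Genes of growth and division were lower as lists after CBL0137, with small changes per gene. MYC target genes of nucleolus and biosynthesis fell in 5 of 46 members (13 adjusted over the list alone, median -0.42), among them Ndufaf4, Utp20, Ddx21 and Wdr43 at -0.67, -0.59, -0.59 and -0.56. Cholesterol biosynthesis genes fell in 2 of 23 members (13 adjusted over the list alone, median -0.46), among them the sterol carrier Stard4 at -0.72. Camera adjusted p were 1.62e-11 and 3.84e-07, and adjusted p = 0.338 with an estimated correlation for both. Mitotic genes had a median of -0.63 with 0 of 40 members past limma's threshold (0 adjusted over the list alone), camera adjusted p = 4.90e-09, and adjusted p = 0.469 with an estimated correlation. DNA replication genes (median -0.25, 0 of 44 members, 0 adjusted over the list alone) had a camera adjusted p of 0.000827 and adjusted p = 0.719 with an estimated correlation. Homologous recombination genes (median -0.27, 0 of 32, 0 adjusted over the list alone) had 0.00268 and adjusted p = 0.590 with an estimated correlation. The heat shock list had a median of -0.24, with Hsph1 at -0.88 as its 1 called member of 20 (1 adjusted over the list alone), camera adjusted p = 0.00935, and adjusted p = 0.469 with an estimated correlation. Its call was lost without vehicle replicate 2 (0.141), and that of the DNA replication list without CBL0137 replicate 3 (0.0676, median -0.14). Mki67 was at 338 ± 64.4 and 220 ± 48.9 TPM (SD, n = 3 each, adjusted p = 0.320).

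Among noradrenergic genes, Dbh, Ddc and Gch1, enzymes and a cofactor enzyme of catecholamine synthesis, and the neuropeptide Npy rose after CBL0137, by 1.69 ± 0.38, 0.65 ± 0.17, 0.88 ± 0.19 and 1.87 ± 0.48 on the log2 scale (SE). The calls of Dbh and Npy were lost without CBL0137 replicate 3 (adjusted p = 0.102 and 0.177), and also without vehicle replicate 2 or 3 or CBL0137 replicate 1 or 2. Those of Ddc and Gch1 were not kept in all leave-one-out fits either. Dbh, Ddc, Gch1 and Npy were 4 of 30 members of the adrenergic identity list (5 adjusted over the list alone). The list's median of 0.13 did not pass (camera adjusted p = 0.273) and was below 0 under quantile normalization. Amino acid synthesis and charging genes Asns, Psat1 and Cars fell by 0.76, 0.75 and 0.80 and their activator Atf4 by 0.54, while Atf3 rose by 1.26, in a stress response list that did not pass (camera adjusted p = 0.164, 1 rose and 4 fell of 25, also adjusted over the list alone). The genes that fell furthest were Mfsd2a, a lysophospholipid transporter, the neurotrophin Bdnf, Kcng2, Fut9, Pbx3, Nfib, Dixdc1 and Mbnl3, at -1.37, -1.33, -1.29, -1.21, -0.99, -0.93, -0.90 and -0.89, with limma adjusted p from 0.00613 to 0.0491. Both FACT subunits, Ssrp1 and Supt16, had changes of -0.31 ± 0.14 and -0.41 ± 0.15 that did not pass (adjusted p = 0.196 and 0.124). Of the chromatin list of histone deacetylases and FACT, 0 of 13 members were called by limma (0 adjusted over the list alone).

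In all, limma called 774 genes that rose and 175 that fell after CBL0137, 653 and 8 of them at least 2-fold. The total of 949 was 547 with a pseudocount of 5, 4692 with array weights, 446, 422 and 324 without vehicle replicate 1, 2 and 3, and 535 without CBL0137 replicate 3. Of 78 calls of named genes, 26 were kept in all 11 leave-one-out fits, among them Ifit1, Isg15, Cxcl10, B2m and Cd274, and 50 were lost without vehicle replicate 3, including Cdkn1a (adjusted p = 0.0549) and H2-K1 (0.0663).

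**Figure D1:**
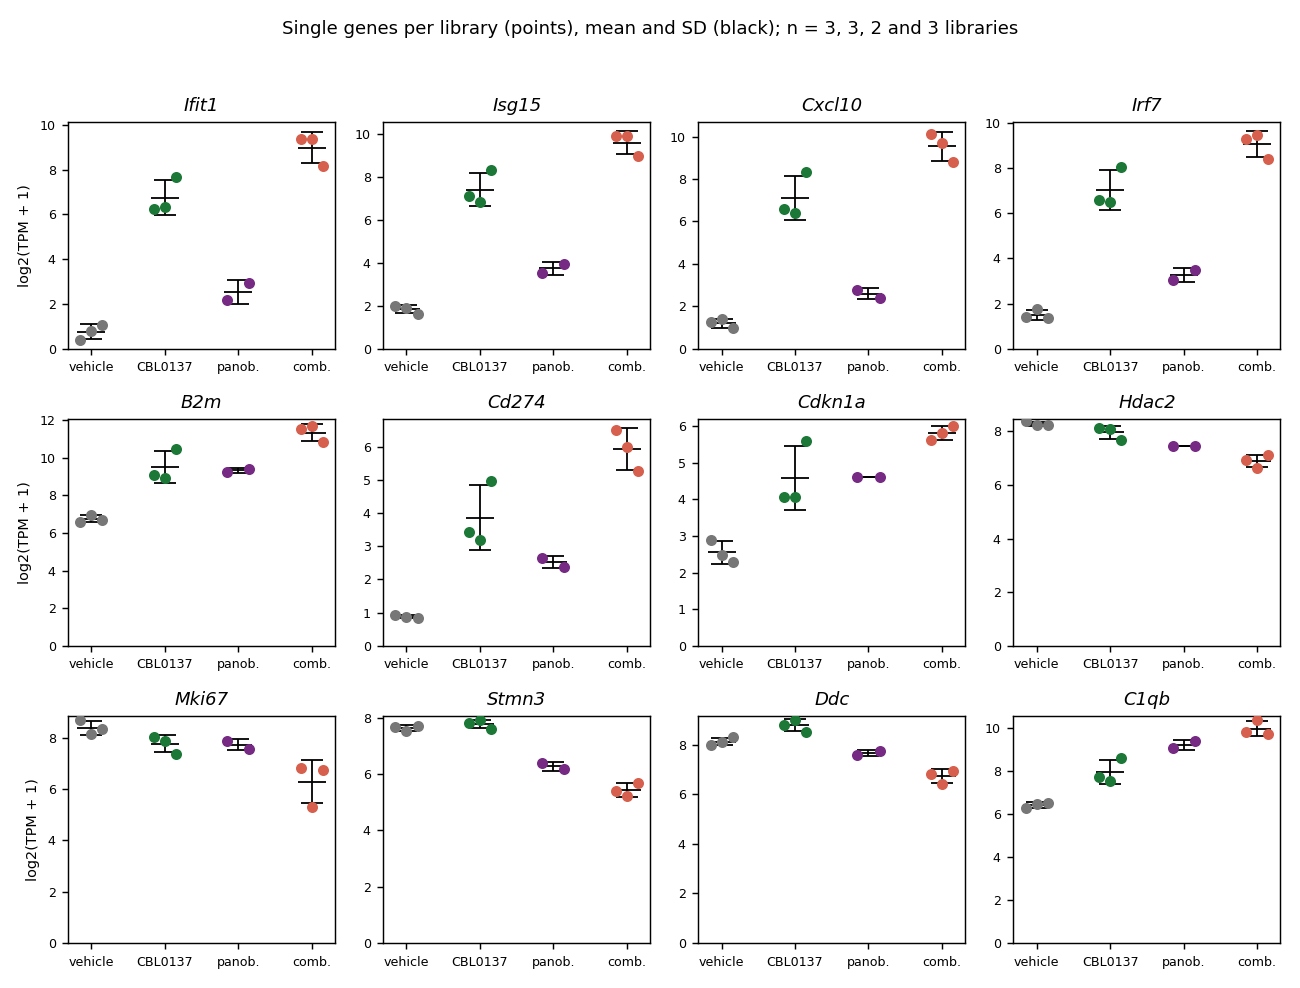
Log2(TPM + 1) of 12 genes in each library (points), with the mean and SD in black, for vehicle (n = 3), CBL0137 (n = 3), panobinostat (n = 2) and the combination (n = 3). Ifit1 averaged 0.713, 119, 5.07 and 538 TPM in these 4 groups, and Mki67 338, 220, 213 and 85.6 TPM.

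The comparison of panobinostat with vehicle asks what changed after an inhibitor of histone deacetylases. Markers of myeloid, vascular and connective tissue cells rose. Macrophage and monocyte markers rose in 21 of 22 members (22 adjusted over the list alone, median 2.72), with the chemokine receptor Ccr2 from 3.19 ± 1.55 (SD, n = 3) to 88.9 ± 12.9 TPM (n = 2), a log2 change of 4.48 ± 0.36 (SE, adjusted p = 0.000238). The complement subunit C1qb, Cd68 and Msr1 rose by 2.80, 2.69 and 3.10. Neutrophil markers rose in 8 of 8 members (8 adjusted over the list alone, median 2.20), and the calgranulins S100a8 and S100a9 rose by 4.92 ± 0.52 and 5.04 ± 0.69. Fibroblast and pericyte markers rose in 19 of 20 (19 adjusted over the list alone, median 2.94), with the collagen Col6a1 at 3.03 and Postn at 3.40. Endothelial markers rose in 17 of 17 (17 adjusted over the list alone, median 2.09), with Vwf at 2.62 and Tek at 2.26. These 4 lists had camera adjusted p of 9.06e-12, 6.14e-05, 1.23e-08 and 3.62e-06, and adjusted p = 0.582 with an estimated correlation for each. In panobinostat replicates 1 and 3 the macrophage median stood at 2.59 and 2.92 above the vehicle mean, and the fibroblast median at 2.84 and 3.02.

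Schwann cell and glial markers rose in 10 of 14 members after panobinostat (10 adjusted over the list alone, median 1.75), with S100b, Sox10, Ngfr and Erbb3 at 2.52, 2.65, 1.99 and 1.79. Dendritic cell markers rose in 5 of 10 (6 adjusted over the list alone, Itgax at 2.25), immediate-early genes in 13 of 19 (16 adjusted over the list alone, Junb at 1.89 and Zfp36 at 2.25) and glucocorticoid-responsive genes in 9 of 13 (9 adjusted over the list alone), with the metallothioneins Mt1 and Mt2 at 1.29 and 1.58 and Cebpd at 2.87. These 4 lists had camera adjusted p of 0.00241, 0.0255, 0.000472 and 0.00280, and adjusted p = 0.582 with an estimated correlation for each. Checkpoint genes rose in 6 of 12 members (6 adjusted over the list alone), among them Havcr2, Cd80 and Lag3 at 1.67, 1.81 and 1.10 and Vsir, listed as 4632428N05Rik, at 2.75, with camera adjusted p = 0.0354, and adjusted p = 0.653 with an estimated correlation. That call was lost without vehicle replicate 1 (0.0574) and without panobinostat replicate 1 (0.0557). T cell markers rose in 4 of 17 members (Thy1, Il7r, Cd4 and Cd28, 3 adjusted over the list alone), while the list's median of 0.54 did not pass (camera adjusted p = 0.170) and fell below 0 under another scaling. The fat markers Fabp4, Adipoq and Plin1 rose by 2.85, 2.62 and 2.26, in a muscle and fat list that did not pass (camera adjusted p = 0.0606, 3 of 12, 2 adjusted over the list alone). That list passed without CBL0137 replicate 1 (0.0412) or 2 (0.0491), panobinostat replicate 1 (0.00667), or combination replicate 1 (0.0473) or 3 (0.0385), and with TMM factors (0.0253).

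Antigen presentation genes rose after panobinostat as well. MHC class II genes rose in 7 of 10 members (7 adjusted over the list alone, median 2.71), with H2-DMb1 at 3.04 and H2-Ab1 at 2.89. MHC class I genes rose in 16 of 19 (16 adjusted over the list alone, median 2.03). B2m rose from 107 ± 14.4 (SD, n = 3) to 644 ± 62.5 TPM (n = 2) and H2-K1 by 2.53 ± 0.49. Interferon-stimulated genes rose in 39 of 47 members (41 adjusted over the list alone, median 1.77), led by Ifi27l2a, Ifitm3, Ifi204 and Bst2 at 4.06, 3.38, 3.13 and 2.77. Ifit1 reached 5.07 ± 2.21 TPM (n = 2, log2 change 1.80 ± 0.48), and Cxcl10, at 5.06 ± 1.12 TPM, did not pass (adjusted p = 0.0597). Chemokines and cytokines rose in 18 of 25 (19 adjusted over the list alone, median 1.85), with Ccl12, Ccl2 and Ccl7 at 4.83, 3.56 and 3.89. NF-kB target genes rose in 19 of 22 (19 adjusted over the list alone, median 1.60, 0.825 quantile-normalized). Bcl2a1b was at 3.20 and Cxcl1 at 2.78. These 5 lists had camera adjusted p of 0.00181, 2.43e-05, 6.35e-09, 3.62e-06 and 6.78e-06, and 0.582 each with an estimated correlation. Ccl9, Timp1 and F13a1 (4.78, 4.47 and 4.43) and Mir1197 completed the furthest rises. Mir1197 was at 0, 47.5 and 0 TPM in vehicle and 127 and 108 TPM after panobinostat.

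Growth and cell cycle genes fell after panobinostat. MYC target genes fell in 36 of 46 members (37 adjusted over the list alone, median -0.81), among them Nop16 and Farsa at -0.86 and -0.68. Mitotic genes fell in 24 of 40 (28 adjusted over the list alone, median -0.99), with the checkpoint gene Mad2l1 at -1.05 and Aspm at -1.15. DNA replication genes fell in 22 of 44 (23 adjusted over the list alone, median -0.75), with Gins4 at -0.72. Cholesterol biosynthesis genes fell in 17 of 23 (17 adjusted over the list alone, median -0.76), with Lss at -1.24 and Idi1 at -1.43. For these 4 lists camera gave adjusted p of 9.45e-13, 9.93e-09, 1.78e-08 and 2.96e-07, and adjusted p = 0.582 with an estimated correlation for each. Homologous recombination genes fell in 7 of 32 (5 adjusted over the list alone, median -0.46), with Atr at -0.65 and Atm at -0.63 and a median of -0.30 without panobinostat replicate 3, camera adjusted p = 0.00151, and adjusted p = 0.653 with an estimated correlation. Histone genes had a median of -0.68, while 2 of 68 members fell (Hist1h4i and Hist1h4n) and 2 rose (0 adjusted over the list alone), camera adjusted p = 5.44e-05, and adjusted p = 0.752 with an estimated correlation. The risen ones were Hist2h2be at 0.68, which turned to -0.19 under quantile normalization, and Hist2h2aa2, which was listed at 0 in all 3 vehicle libraries. Heat shock genes went both ways, with 13 of 20 falling and 5 rising (13 and 5 adjusted over the list alone, median -0.47, mean 0.21). The chaperones Hsp90aa1, Dnaja1 and Hspd1 fell by 1.10, 0.85 and 1.17 and the small heat shock proteins Hspb1 and Cryab rose by 4.24 and 3.90. Camera put the heat shock list down (adjusted p = 0.00376), and adjusted p = 0.582 with an estimated correlation.

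Deacetylase and FACT genes changed in part after panobinostat. Hdac2 (chromosome 10, 36974297 to 37001889) fell from 311 ± 17.2 (SD, n = 3) to 174 ± 2.11 TPM (n = 2), a log2 change of -0.83 ± 0.16 (SE, adjusted p = 0.00265), and Hdac3, Ssrp1 and Supt16 fell by 0.34, 0.78 and 0.71. Hdac8 rose by 0.49 (-0.17 quantile-normalized). The histone deacetylase and FACT list did not pass (camera adjusted p = 0.158). Of 13, 4 fell and 1 rose, also adjusted over the list alone. Hdac1 was at -0.33 ± 0.14 (adjusted p = 0.0724), and H1f0, a linker histone gene known to rise with deacetylase inhibitors, at 0.50 ± 0.24 (adjusted p = 0.113). Cdkn1a rose to 23.5 ± 0.0495 TPM (n = 2), a log2 change of 2.06 ± 0.40. In the p53 list 18 of 36 members rose and 5 fell (19 and 5 adjusted over the list alone, median 0.61, 0.195 quantile-normalized). Phlda3, Pltp and Fas were at 1.80, 2.32 and 2.50 and Bloc1s2 at -0.76. The list did not pass (camera adjusted p = 0.121, and 0.0412 without CBL0137 replicate 3). Casp8, Bak1 and Pmaip1 rose by 2.35, 1.79 and 1.63, while the apoptosis list did not pass (camera adjusted p = 0.734, 6 of 24 rose and 4 fell, also adjusted over the list alone).

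Neuronal genes were split after panobinostat. The microtubule regulator Stmn3 fell by 1.36 (8 of 30 members fell, 8 adjusted over the list alone), and Vip and Ntrk2 rose by 2.19 and 1.26 (5 rose, 6 adjusted over the list alone). The list's median of -0.17 did not pass (camera adjusted p = 0.138). Of the adrenergic list Cyb561, Lin28b and Gata3 fell by 0.66, 1.07 and 0.87 (3 of 30, 1 adjusted over the list alone), and its median was -0.19 and its mean 0.04 (camera adjusted p = 0.305). Th was at 168 ± 66.7 TPM (SD, n = 2) and did not pass (adjusted p = 0.622). The stress response genes Psat1, Asns and Cars fell by 1.16, 0.97 and 0.92 and Atf3 rose by 1.68, in a list with a median of 0.10 (-0.03 with TMM factors and with quantile normalization) that camera put down and that did not pass (adjusted p = 0.852, 6 of 25 rose and 5 fell, also adjusted over the list alone). The furthest falls were Fut9, Gcat, Ppp1r17, Lmo3, the acetyl-CoA acetyltransferase Acat2, Dach1, Cenpv and Kcnip1, from -1.95 to -1.48, with limma adjusted p from 0.000458 to 0.00321.

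In all, limma called 3959 genes that rose and 2613 that fell after panobinostat, 2878 and 267 of them at least 2-fold. With TMM factors the counts were 3651 and 3669 and with quantile normalization 2451 and 3960, with the median of all genes shifted by -0.12 and -0.28. Without panobinostat replicate 3, the library with skeletal muscle transcripts, 4031 genes were called, and 26 of 139 calls of named genes were lost.

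**Figure D2:**
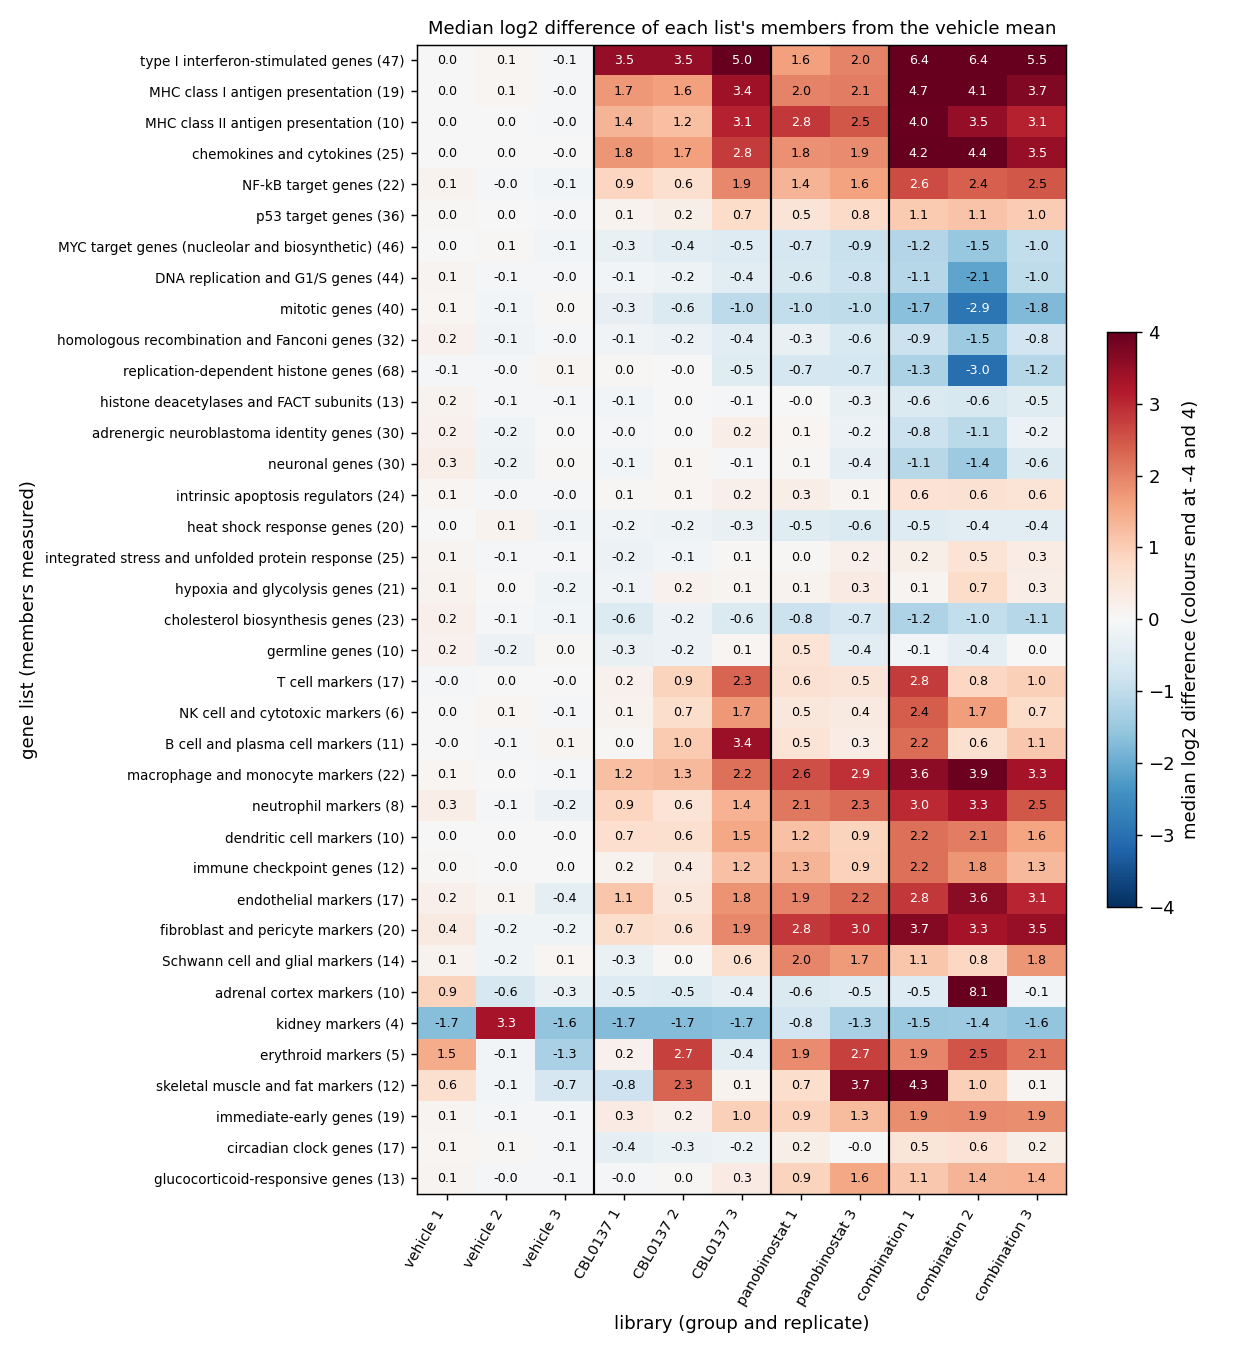
Median over each list's members of the log2(TPM + 1) difference from the vehicle mean, for 37 gene lists (vertical axis, members measured in parentheses) and 11 libraries (horizontal axis), with colours ending at -4 and 4. Interferon-stimulated genes stand at 3.52 to 4.96 in the CBL0137 libraries, 1.64 and 1.98 in the panobinostat libraries and 5.47 to 6.40 in the combination libraries.

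The comparison of the combination with vehicle asks what both drugs together changed. Interferon-stimulated genes rose in 47 of 47 members (47 adjusted over the list alone), with a median log2 change of 6.13. Ifit3 rose from 1.63 ± 0.426 to 1422 ± 580 TPM and Cxcl10 (chromosome 5, 92346638 to 92348889) from 1.31 ± 0.333 to 800 ± 347 TPM (SD, n = 3 each), log2 changes of 8.99 ± 0.43 and 8.34 ± 0.48 (SE) with limma adjusted p of 1.74e-06 and 3.23e-06. Ccl12, Ifit1bl1, Ifit1, Ifit3b and Slfn4 rose by 8.83, 8.49, 8.22, 8.12 and 8.03, and Isg15, Usp18 and Irf7 by 7.75, 7.51 and 7.55. MHC class I genes rose in 19 of 19 members (19 adjusted over the list alone, median 4.21), with B2m from 107 ± 14.4 to 2678 ± 775 TPM and Psmb8, Tap1 and H2-T23 at 5.33, 5.78 and 5.14. Chemokines and cytokines rose in 25 of 25 (25 adjusted over the list alone, median 3.94), with Ccl2 at 5.60 and Ccl4 at 5.61. NF-kB target genes rose in 21 of 22 (21 adjusted over the list alone, median 2.59), with Vcam1 at 3.15 and Il6 at 2.75, and MHC class II genes in 8 of 10 (9 adjusted over the list alone, median 3.55). By camera the adjusted p of these 5 lists were 3.80e-20, 2.68e-08, 3.24e-09, 8.66e-07 and 0.00216, and 0.480 each with an estimated correlation. The interferon median of combination replicates 1, 2 and 3 was 6.40, 6.38 and 5.47 above the vehicle mean.

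Markers of immune, vascular and connective tissue cells rose after the combination. Macrophage and monocyte markers rose in 22 of 22 members (22 adjusted over the list alone, median 3.60), with Ly6c2 from 0.923 ± 1.12 to 343 ± 171 TPM (SD, n = 3 each) and Fcgr1 and Msr1 at 5.76 and 4.09. Neutrophil markers rose in 8 of 8 (8 adjusted over the list alone, median 2.94), with S100a8 and S100a9 at 5.97 each. Dendritic cell markers rose in 8 of 10 with 1 falling (9 and 1 adjusted over the list alone), with Clec9a at 2.58 and Fscn1 at -1.21. Endothelial markers rose in 17 of 17 (17 adjusted over the list alone, median 3.24), with Pecam1 at 3.22. Fibroblast and pericyte markers rose in 19 of 20 with 1 falling (19 and 1 adjusted over the list alone, median 3.53), with Col1a2 at 3.74. Schwann cell and glial markers rose in 9 of 14 with 1 falling (9 and 1 adjusted over the list alone, median 1.25), with Cnp at 1.67. Checkpoint genes rose in 9 of 12 (10 adjusted over the list alone), with Cd274 at 63.5 ± 26.5 TPM against 0.843 ± 0.0651 in vehicle, a log2 change of 5.04 ± 0.44. The 7 camera adjusted p were 1.60e-09, 0.000685, 0.0156, 9.21e-07, 9.48e-07, 0.0432 and 0.00335 in this order, and 0.480 each with an estimated correlation. T cell markers rose in 9 of 17 (6 adjusted over the list alone), with Cd4 at 2.48, camera adjusted p = 0.0108, and adjusted p = 0.586 with an estimated correlation. The T cell median was 2.80 in combination replicate 1, the library with B cell transcripts, and 0.82 and 0.96 in replicates 2 and 3, and without replicate 1 the list's median was 0.91. The Schwann call was lost without vehicle replicate 1 (0.0573) or 2 (0.0617), either panobinostat replicate (0.0543 each) or combination replicate 3 (0.0745). Cd8a rose by 1.07 ± 0.41, to 1.87 ± 1.54 TPM, and its call was lost without any 1 vehicle library (adjusted p = 0.0898, 0.0577 and 0.106), CBL0137 replicate 2 (0.0547) or combination replicate 1 (log2 change 0.66, 0.156).

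Lymphocyte and fat markers rose in smaller numbers after the combination. NK cell markers rose in 5 of 6 members (6 adjusted over the list alone), Klrk1 by 1.88, and B cell markers in Cd22 alone of 11 (1 adjusted over the list alone), while neither list passed (camera adjusted p = 0.0870 and 0.186, the former 0.0311 without combination replicate 3). Gzmb, which encodes granzyme B, was listed at 0 in all 3 vehicle libraries and at 8.93, 3.95 and 0.830 TPM in combination replicates 1, 2 and 3. Fabp4, Adipoq, Cidec and Plin1 rose by 3.74, 3.97, 3.75 and 3.53 (6 of 12 muscle and fat members, 6 adjusted over the list alone, camera adjusted p = 0.129). Adrenal cortex markers rose in Mrap, Mc2r and Scarb1 (3 of 10, 3 adjusted over the list alone), in a list that did not pass (camera adjusted p = 0.186) and whose median stood at 8.09 in combination replicate 2 against -0.52 and -0.11 in replicates 1 and 3.

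Proliferation genes fell after the combination. Mitotic genes fell in 40 of 40 members (40 adjusted over the list alone, median -2.14), with Cdc25c, Cenpa and Aspm at -2.97, -2.25 and -2.24 and Mki67 from 338 ± 64.4 to 85.6 ± 40.9 TPM (SD, n = 3 each). DNA replication genes fell in 43 of 44 (44 adjusted over the list alone, median -1.48), with Dut and Orc6 at -2.18 and -1.63. Homologous recombination genes fell in 24 of 32 with 1 rising (24 and 1 adjusted over the list alone, median -1.06), with Rad54l at -1.89 and Fancm at -1.66. Histone genes fell in 62 of 68 (62 falling and 1 rising adjusted over the list alone, median -1.78), with Hist4h4 and Hist2h4 at -1.76 and -1.77. MYC target genes fell in 40 of 46 with 1 rising (41 and 1 adjusted over the list alone, median -1.20), with Nop16, Tmem97 and the polyamine enzyme Odc1 at -1.55, -1.80 and -1.20. Cholesterol biosynthesis genes fell in 18 of 23 (18 adjusted over the list alone, median -1.04), with Sqle and Cyp51 at -1.82 and -1.86. By camera the adjusted p of these 6 lists were 2.15e-12, 2.21e-11, 6.67e-06, 3.03e-10, 3.40e-12 and 1.53e-06, and 0.480 each with an estimated correlation. In combination replicate 2, the library with adrenal cortex transcripts, the mitotic median was -2.89 and the histone median -3.01, against -1.67 and -1.78, and -1.26 and -1.15, in replicates 1 and 3.

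Sympathetic neuroblast genes moved in both directions after the combination. The regulators Isl1 and Lin28b fell by 1.73 and 1.97 on the log2 scale and the decarboxylase Ddc and Cyb561 by 1.40 and 1.21, while Th (chromosome 7, 142892779 to 142899995), Dbh and Npy rose by 1.04, 1.46 and 2.65 (15 of 30 adrenergic members fell and 6 rose, also adjusted over the list alone, median -0.76). Th was at 150, 416 and 329 TPM and Npy at 40.1, 187 and 56.0 TPM in combination replicates 1, 2 and 3, of which replicate 2 held adrenal cortex transcripts. The Th call was lost without vehicle replicate 2 or 3 (adjusted p = 0.105 and 0.0670) and without combination replicate 2 or 3 (0.112 and 0.0860). Neuronal genes fell in 20 of 30 members and rose in 5 (20 and 5 adjusted over the list alone, median -1.04), with the stathmins Stmn2, Stmn3 and Stmn4 at -1.86, -2.20 and -2.36. Camera adjusted p were 0.0346 and 0.00178, and adjusted p = 0.514 with an estimated correlation for both. The adrenergic call was lost without combination replicate 1 (0.0733) and with TMM factors (0.0614), and its median was -0.50 without vehicle replicate 1. Mycn, the mouse gene (chromosome 12, 12936093 to 12941836; the human transgene is not analysed here), was at 6.03 ± 0.393 TPM in vehicle and 6.79 ± 4.56 TPM after the combination (SD, n = 3 each, adjusted p = 0.980).

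Chromatin and stress genes changed after the combination. Hdac2, Ssrp1, Supt16 and Hdac3 fell by 1.39, 1.14, 1.12 and 0.57, and Hdac7 and Hdac8 rose by 0.83 and 0.36, the latter at -0.30 under quantile normalization (8 of 13 fell and 2 rose, also adjusted over the list alone). Hdac1, at 47.1 ± 4.21 TPM, had a change of 0.03 that did not pass (adjusted p = 0.855) and was below 0 under each of 3 other scalings. Cdkn1a rose to 56.0 ± 7.36 TPM (SD, n = 3), a log2 change of 3.27 ± 0.36 (SE, adjusted p = 3.57e-05), and Mdm2 by 0.35 ± 0.12, a call lost without vehicle replicate 2 (0.105) or 3 (0.0659) or any 1 combination library (0.0518 to 0.0607). The p53 list rose in 24 of 36 members with 5 falling (24 and 5 adjusted over the list alone, median 1.03), with Gdf15 and Pmaip1 at 3.16 and 2.98. Immediate-early genes rose in 16 of 19 with 1 falling (16 and 1 adjusted over the list alone, median 1.79), with Zfp36 and Klf6 at 3.71 and 2.15. Glucocorticoid-responsive genes rose in 9 of 13 (9 adjusted over the list alone, median 1.43), with the lipocalin Lcn2 at 5.79. Heat shock genes fell in 14 of 20 and rose in 5 (also adjusted over the list alone, median -0.43, mean 0.29), with Fkbp4 at -1.76 and Hspa1b at 2.76. Camera adjusted p for the histone deacetylase and FACT, p53, immediate-early, glucocorticoid and heat shock lists were 0.0362, 0.00253, 0.000274, 0.0181 and 0.0370, and adjusted p = 0.480 with an estimated correlation for each. The first of these calls was lost without vehicle replicate 1 (0.0555), and the last with TMM factors (0.0835) and without vehicle replicate 2 (0.0766), panobinostat replicate 1 (0.0608) or panobinostat replicate 3 (0.0611).

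Apoptosis regulators went both ways after the combination, with Casp8, Bak1 and Bcl2l1 rising by 4.10, 2.94 and 1.17 and Birc5 falling by 2.28 (13 of 24 rose and 4 fell, also adjusted over the list alone, camera adjusted p = 0.129). In the stress response list Atf3 and Slc3a2 rose by 3.08 and 1.05 and Psat1 and Asns fell by 1.71 and 1.37 (13 of 25 rose and 6 fell, also adjusted over the list alone, camera adjusted p = 0.591). Among the furthest falls were Dusp9, Ppp1r17 and Kcnip1 at -3.01, -3.37 and -3.05, and 5 small RNA genes, which may rest on few reads. Snora75 was listed at 530, 64.5 and 206 TPM in vehicle and at 0 in all 3 combination libraries, and Scarna8 at 182, 110 and 177 TPM and at 0. Snora41, Mir1983 and Snora69 averaged 402 ± 116, 102 ± 57.7 and 102 ± 29.2 TPM in vehicle and 79.5 ± 138, 10.9 ± 18.8 and 25.3 ± 43.8 TPM after the combination (SD, n = 3 each), and the calls of these 3 were lost without vehicle replicate 2 (adjusted p = 0.103, 0.0654 and 0.0708) and in 3 or more other leave-one-out fits each.

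In all, limma called 5568 genes that rose and 4666 that fell after the combination, 3921 and 1770 of them at least 2-fold. With quantile normalization the counts were 4162 and 6678; the median of all genes shifted by -0.17, -0.35 and -0.12 with TMM factors, quantile normalization and rescaling without small RNA and histone genes. Of 158 calls of named genes 145 were kept in all leave-one-out fits, and 10 were lost without vehicle replicate 2.

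**Figure D3:**
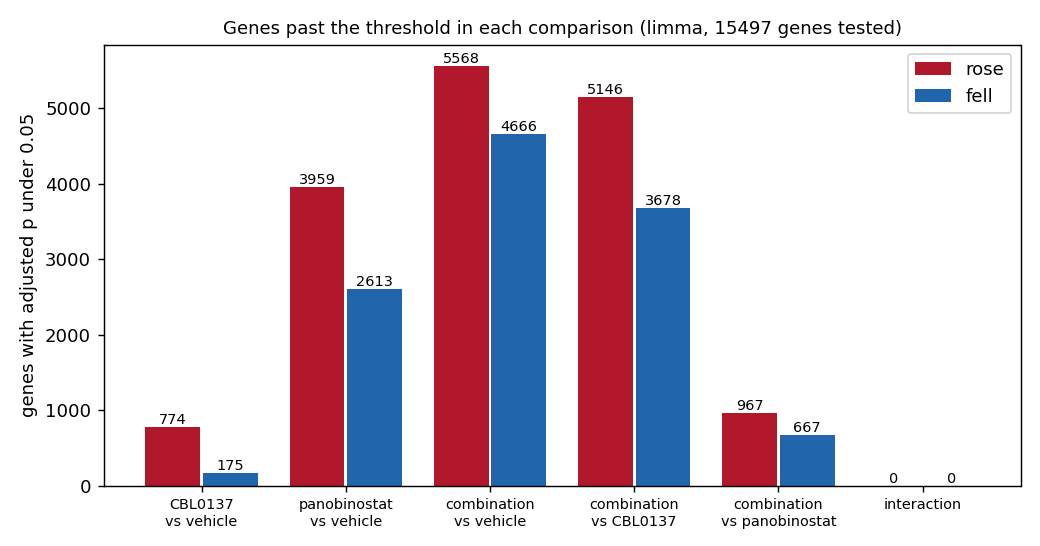
Number of genes past the limma threshold that rose and fell in each comparison, with bars starting at 0, out of 15497 genes tested. The combination against vehicle had 5568 rises and 4666 falls, and the interaction had 0 of either.

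The comparison of the combination with CBL0137 alone asks what panobinostat added. Stromal and myeloid markers were higher with both drugs: fibroblast and pericyte markers rose in 19 of 20 members (19 rising and 1 falling adjusted over the list alone, median 2.27), endothelial markers in 17 of 17 (17 adjusted over the list alone, median 2.08) and macrophage markers in 21 of 22 (21 adjusted over the list alone, median 2.08). Pdgfrb, Col6a3 and Col1a2 rose by 3.12, 2.75 and 2.77, Vwf by 2.61, and Ccr2 by 3.14. Neutrophil markers rose in 7 of 8 (7 adjusted over the list alone), with S100a9 at 3.74 ± 0.62 (SE) and S100a8 at 3.42 ± 0.46. Checkpoint genes rose in 7 of 12 (7 adjusted over the list alone). Schwann cell markers rose in 8 of 14 (8 adjusted over the list alone, median 0.90). The 6 camera adjusted p, in the order named, were 6.85e-06, 6.85e-06, 9.19e-08, 0.00156, 0.0130 and 0.0422, and 0.498 each with an estimated correlation. The Schwann call was lost without CBL0137 replicate 1 (0.0638) and without combination replicate 3 (0.0912).

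Interferon-stimulated genes were higher with both drugs than with CBL0137 in 46 of 47 members (47 adjusted over the list alone, median 2.12), with Oas3, Dhx58, Ifih1 and Ifi204 at 2.68, 2.45, 2.42 and 2.41 and Ifit1 at 538 ± 216 against 119 ± 71.1 TPM (SD, n = 3 each). MHC class I genes rose in 18 of 19 (18 adjusted over the list alone, median 1.87), with Tap2 at 2.53. Chemokines rose in 20 of 25 (21 adjusted over the list alone, median 1.95), with Cx3cl1 at 2.63 and Il18 at 2.04, and NF-kB target genes rose in 18 of 22 (19 adjusted over the list alone, median 1.33), with Bcl3 at 1.70. Immediate-early genes rose in 14 of 19 (14 adjusted over the list alone, median 1.35), with Klf4 at 1.73. Glucocorticoid-responsive genes rose in 9 of 13 (9 adjusted over the list alone, median 1.33), with Klf9 at 1.33 and Sgk1 at 1.50. Camera adjusted p for these 6 lists were 1.16e-10, 3.50e-05, 1.31e-05, 0.000131, 0.00105 and 0.00686, and 0.498 each with an estimated correlation. The p53 list rose in 24 of 36 and fell in 5 (also adjusted over the list alone, median 0.94), with Tnfrsf10b at 1.58 and Cdkn1a at 1.24 ± 0.36 (adjusted p = 0.0589 and 0.0579 without CBL0137 replicates 1 and 2), camera adjusted p = 0.0225, and adjusted p = 0.589 with an estimated correlation. That call was lost without combination replicate 3 (0.0552). MHC class II genes rose in 7 of 10 (7 adjusted over the list alone) and the list did not pass (camera adjusted p = 0.0503), but did with TMM factors (0.0211) and without CBL0137 replicate 3 (0.000908), combination replicate 2 (0.0376) or combination replicate 3 (0.0373).

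Neuronal, adrenergic and proliferation genes were lower with both drugs than with CBL0137. Neuronal genes fell in 18 of 30 members with 3 rising (20 and 3 adjusted over the list alone, median -0.91), with Stmn3 from 218 ± 22.6 to 42.6 ± 7.41 TPM (SD, n = 3 each), a log2 change of -2.34 ± 0.13 (SE, adjusted p = 0.000135), and Gap43 at -1.67. Adrenergic genes fell in 16 of 30 (16 adjusted over the list alone, median -0.70), with Ddc at -2.05 ± 0.17, Cyb561 at -1.30 and Dlk1 at -1.35. Th, at 293 ± 47.0 and 298 ± 135 TPM, did not pass (adjusted p = 0.868). Mitotic genes fell in 39 of 40 (39 adjusted over the list alone, median -1.51), DNA replication genes in 40 of 44 (44 adjusted over the list alone, median -1.20). Histone genes fell in 62 of 68 with 1 rising (62 and 2 adjusted over the list alone, median -1.64, and -1.07 without combination replicate 2) and homologous recombination genes in 20 of 32 with 1 rising (20 and 1 adjusted over the list alone, median -0.73). MYC target genes fell in 38 of 46 with 1 rising (39 and 1 adjusted over the list alone, median -0.71), with Cdk4 at -1.39 and Fbl at -1.12. Cholesterol genes fell in 14 of 23 (14 adjusted over the list alone, median -0.60), and histone deacetylase and FACT genes in 8 of 13 with 2 rising (also adjusted over the list alone), with Hdac2 at -1.07. In this order the 9 camera adjusted p were 3.50e-05, 0.000240, 2.05e-12, 1.12e-12, 1.12e-12, 1.31e-05, 7.40e-11, 3.50e-05 and 0.0157, and 0.498 each with an estimated correlation.

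Saa1, Gsta4 and Adh1 were among the furthest rises over CBL0137 alone, at 3.69 ± 1.09, 3.69 ± 0.57 and 3.95 ± 1.21 (SE). Adh1 was at 441 TPM in combination replicate 2 and at 32.7 and 6.65 TPM in replicates 1 and 3. Orm2 was listed at 0.310, 0.930 and 1.26 TPM after CBL0137 and at 24.2, 20.6 and 23.8 TPM after the combination. The furthest falls were Agtr2, Ppp1r17 and Stmn4, at -2.60, -2.52 and -2.46, and the small RNA genes Snora2b and Mir1197. Both were at 0 in all 3 combination libraries against 77.4 to 83.7 and 41.2 to 44.4 TPM after CBL0137. Apoptosis genes (11 of 24 rose and 4 fell, 12 and 4 adjusted over the list alone), with the BH3-only gene Hrk at -2.07 and Mcl1 at 0.89, did not pass as a list (camera adjusted p = 0.312). Neither did heat shock (6 of 20 rose and 10 fell, also adjusted over the list alone, median -0.28, mean 0.31, camera adjusted p = 0.131) or stress response genes (11 of 25 rose and 2 fell, also adjusted over the list alone, camera adjusted p = 0.240), with Xbp1 and Edem1 at 0.94 and 1.09. Limma called 5146 genes that rose and 3678 that fell, 3229 and 1101 of them at least 2-fold. With TMM factors these were 4389 and 5018 and with quantile normalization 3892 and 5361, with the median of all genes shifted by -0.17 and -0.25. Of 154 calls of named genes 143 were kept in all leave-one-out fits, and 10 were lost without CBL0137 replicate 1.

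The comparison of the combination with panobinostat alone asks what CBL0137 added. Interferon-stimulated genes rose in 46 of 47 members (47 adjusted over the list alone, median 4.15), with Ifit1bl1, Ifit3, Ifit3b, Ifit1 and Ifi44 at 7.32, 6.78, 6.49, 6.42 and 5.49 and limma adjusted p of 0.000177 each. Cxcl10 rose from 5.06 ± 1.12 (SD, n = 2) to 800 ± 347 TPM (n = 3), a log2 change of 6.96 ± 0.53 (SE), and Cxcl11, Cxcl9 and Ccl4 by 5.08, 5.08 and 3.75 (16 of 25 chemokines and cytokines, 19 adjusted over the list alone, median 1.98). MHC class I genes rose in 18 of 19 (19 adjusted over the list alone, median 2.41), with Tap1, Psmb9 and Psmb10 at 3.58, 3.03 and 2.70. Cd274 rose by 3.40 ± 0.49. NF-kB genes rose in 3 of 22 (Tnf, Il6 and the chemokine list's Ccl2, 14 adjusted over the list alone, median 0.99). The p53 target genes rose in 7 of 36 (13 adjusted over the list alone, median 0.57), with Mdm2 at 0.64 ± 0.14 and Plk2 at 0.84, and apoptosis regulators rose in 7 of 24 with 2 falling (9 and 2 adjusted over the list alone), with Casp8 at 1.76. Camera adjusted p of these lists in this order were 2.36e-49, 7.25e-12, 5.21e-14, 3.47e-06, 2.69e-05 and 0.00723, and 0.512 each with an estimated correlation. Cdkn1a, at 1.21 ± 0.40, did not pass (adjusted p = 0.0738).

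Monocyte and vascular markers differed between the combination and panobinostat alone. Macrophage and monocyte markers rose in 6 of 22 members with 1 falling (9 and 1 adjusted over the list alone, median 0.73), with Ly6c2 at 4.08, Fcgr1 at 2.52 and Cx3cr1 at -1.46. Endothelial markers rose in 3 of 17 (Egfl7, Kdr and Plvap, 16 adjusted over the list alone, median 1.19). Checkpoint genes rose in Cd274 alone of 12 (3 adjusted over the list alone), immediate-early genes in 3 of 19 (Klf6, Zfp36 and Atf3, 6 adjusted over the list alone) and NK cell markers in Klrk1 alone of 6 (2 adjusted over the list alone). The 5 camera adjusted p were 5.19e-05, 1.37e-06, 0.00293, 0.00293 and 0.0198, and 0.512 each with an estimated correlation. MHC class II, T cell, fibroblast and adrenal cortex lists had 0 members past limma's threshold (0 adjusted over the list alone for each), medians of 0.80, 1.00, 0.73 and 2.88, camera adjusted p of 0.0371, 0.00669, 0.0140 and 0.0229, and adjusted p = 0.617, 0.611, 0.593 and 0.611 with an estimated correlation. Without combination replicate 1 the calls of the MHC class II, T cell and NK cell lists were lost (0.247, 0.197 and 0.0965, with medians of 0.59, 0.38 and 0.61), and the adrenal cortex median was 4.40. Lost as well were, without panobinostat replicate 1, those of the fibroblast and adrenal cortex lists (0.126 and 0.0507), without panobinostat replicate 3 those of the MHC class II and adrenal cortex lists (0.112 and 0.0530), and without combination replicate 2 that of the adrenal cortex list (0.329, median 0.40).

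Division and identity genes were lower with both drugs than with panobinostat, but no named call of theirs was kept in all leave-one-out fits. Mitotic genes fell in 17 of 40 members (38 adjusted over the list alone, median -1.14), with Cdc25c and Cenpa at -1.66 and -1.22 and Mki67 at -1.44 ± 0.40 (SE). DNA replication, homologous recombination and histone genes fell in 1 each (Dut, Chek2 and Hist1h2bc, with 26 of 44, 9 of 32 and 0 of 68 adjusted over the list alone), with medians of -0.73, -0.63 and -1.11. Neuronal genes fell in 9 of 30 (13 adjusted over the list alone, median -0.72), with Stmn3, Gap43 and Dcx at -0.84, -1.14 and -1.63. Adrenergic genes fell in 9 of 30 with Gch1 rising (14 and 2 adjusted over the list alone, median -0.78), with Hand2 at -1.21. MYC target genes fell in 5 of 46 (8 adjusted over the list alone, median -0.39), cholesterol genes in 5 of 23 (5 adjusted over the list alone, median -0.25), and Hdac9 and Hdac2 by 0.73 and 0.56 (2 of 13, 2 adjusted over the list alone). In this order, ending with the deacetylase list, camera adjusted p were 5.21e-14, 2.75e-10, 1.52e-05, 3.99e-12, 2.07e-06, 0.00356, 9.05e-07, 0.00395 and 0.0152. With an estimated correlation each was 0.512. The last call was lost without panobinostat replicate 1 (0.122). Without combination replicate 2 the mitotic, DNA replication, homologous recombination, histone and cholesterol medians were -0.76, -0.39, -0.39, -0.55 and -0.50, and the cholesterol median was -0.14 without combination replicate 1. The furthest falls held the muscle genes Actn2, Murc and Myh3, at -2.59, -2.27 and -2.22, and Adprhl1 at -1.99, with Actn2 at 42.4 ± 47.8 TPM after panobinostat (SD, n = 2), the group with the muscle-bearing library.

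In all, limma called 967 genes that rose and 667 that fell between the combination and panobinostat, 593 and 260 of them at least 2-fold. With quantile normalization the counts were 1502 and 1825 and with rescaling 691 and 1338, the latter with the median of all genes shifted by -0.14. The total of 1634 was 477 with only these groups in the fit and 102 without panobinostat replicate 3 and combination replicate 2, a pair chosen after seeing the data. Leaving out vehicle replicates 1, 2 and 3 gave 969, 821 and 641, CBL0137 replicates 1 and 3 gave 988 and 2617, panobinostat replicates 1 and 3 gave 366 and 386, and combination replicates 1, 2 and 3 gave 526, 486 and 3356. Of 84 calls of named genes, 60 were lost without panobinostat replicate 1.

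The interaction asks whether the change after both drugs departed from the sum of the changes after each, on the log2 scale. By limma, 0 of 15497 genes passed, with a lowest adjusted p of 0.304, while 1631 genes had an unadjusted p under 0.05, where chance expects 775. The interferon list had a median departure of 0.29 (camera adjusted p = 0.0722), and passed without CBL0137 replicate 3 (0.76, 1.05e-08), combination replicate 3 (0.000243), panobinostat replicate 3 (0.0120) or vehicle replicate 1 (0.0197), and with TMM factors (0.0432). Its median was 0.93 under quantile normalization and 0.09 with rescaling. Lists below the sum were MHC class II genes (median -1.01), neuronal and adrenergic genes (-0.74 and -0.71), histone, mitotic and DNA replication genes (-0.97, -0.51 and -0.45), homologous recombination genes (-0.29), macrophage markers (-0.79) and fibroblast markers (-0.49). Lists above the sum were the heat shock and stress response genes (0.26 and 0.30) and adrenal cortex markers (3.35). For these 12 of 36 lists camera adjusted p ran from 1.91e-11 to 0.0318, and adjusted p = 0.936 with an estimated correlation for each; adjusted over the list alone, 7 neuronal, 1 adrenergic and 1 heat shock gene passed. Without combination replicate 2 the calls of the mitotic, DNA replication and homologous recombination lists were lost (0.320, 0.0885 and 0.528), with medians of -0.10, -0.14 and -0.10, that of the MHC class II list as well (0.0776), and the histone and adrenal cortex medians were -0.38 and 0.80. Without CBL0137 replicate 3 the MHC class II, macrophage and fibroblast medians were -0.37, -0.43 and -0.27. The mitotic median was -0.31 without CBL0137 replicate 1, and the homologous recombination median -0.18 and -0.48 without panobinostat replicates 1 and 3. The MHC class II call was also lost without vehicle replicate 1 (0.0596), CBL0137 replicate 3 (0.207), panobinostat replicate 1 (0.0853) or combination replicate 3 (0.187), and that of homologous recombination without vehicle replicate 2 (0.0783), CBL0137 replicate 1 (0.147) or panobinostat replicate 1 (0.308). The heat shock call was lost without vehicle replicate 2 (0.130), panobinostat replicate 1 (0.210) or combination replicate 3 (0.0751), and the fibroblast call without vehicle replicate 2 (0.0789), CBL0137 replicate 3 (0.575), panobinostat replicate 3 (0.339) or combination replicate 3 (0.0751). With array weights 11 genes were called, and 45, 8, 2 and 1 without panobinostat replicate 1, combination replicate 3, vehicle replicate 2 and CBL0137 replicate 1.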

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

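The interaction tests and the tests of TPM scaling and of other splits of the libraries were set before their results were seen, and all other tests in this part were chosen only after the result was seen. The interaction test of the difference between drug effects set apart 12 lists, each with adjusted p = 0.936 with an estimated correlation. Medians below the sum of the single-drug changes were -1.01 for MHC class II, -0.45 for DNA replication, -0.51 for mitotic, -0.29 for homologous recombination and -0.97 for histone genes. They were -0.71 for adrenergic genes, -0.74 for neuronal genes, -0.79 for macrophage markers and -0.49 for fibroblast markers. Medians above the sum were 0.26 for heat shock genes, 0.30 for stress response genes and 3.35 for adrenal cortex markers, the last 0.80 without combination replicate 2. Without that library the DNA replication, mitotic, homologous recombination and histone medians were -0.14, -0.10, -0.10 and -0.38, and without CBL0137 replicate 3 those of MHC class II, macrophage and fibroblast genes were -0.37, -0.43 and -0.27. The mitotic median was -0.31 without CBL0137 replicate 1.

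Interferon-stimulated genes were higher in all 6 CBL0137 and combination libraries. An even rise of immune and stromal cells is argued against. The interferon median exceeded the highest marker median by 2.31, 2.21 and 1.53 in the CBL0137 libraries. It did so by 2.73, 2.46 and 1.99 with both drugs. It lay below in both panobinostat libraries (-1.21 and -1.04). Ly6c2 outran it after CBL0137, so growth of a subset stays open. Scaling of TPM is argued against, since the lowest interferon median over 4 scalings and both comparisons was 3.67. It stays open whether tumour cells, infiltrating cells or both carried the response, and interferon signalling within the tumour after CBL0137 is a candidate explanation found and tested on the same data.

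Stromal and immune markers were higher, and proliferation genes lower, after the combination. Neighbouring tissue in any 1 library is argued against, since macrophage, endothelial and fibroblast medians kept at least 92.2% without it. Fat in all 3 combination libraries stays open (Adipoq 105 to 496 TPM, vehicle 8.44 to 22.5). For markers a lower tumour share cannot be told apart from changes within cell types, since log2(TPM + 1) compresses low lists. By permutation their lists lay apart (p = 0.0301). In 10 selections made after seeing the data, p was 3e-05 to 0.479 (members of at least 10 TPM, no Schwann list), 9 under 0.05. As the whole cause of the fall in proliferation genes it is argued against, since 152 mitotic, DNA replication and histone genes had a median of -1.79 and 60 adrenergic and neuronal genes one of -0.96 (permutation p = 1e-05, the smallest value the permutations can give), with -1.26 and -0.76 without combination replicate 2, which held adrenal transcripts, and the narrowest gap in replicate 1, at -1.31 and -0.96 (p = 1e-05 for each). A lower tumour share together with fewer dividing cells may account for both.

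CBL0137 replicate 3 stood apart from CBL0137 replicates 1 and 2. A combination library under a wrong label is argued against, since on 951 genes moved by panobinostat it sat at 0.355 between the other CBL0137 libraries (0) and the combination (1), whose libraries sat at 0.919 to 1.10. Lymphoid tissue diluting the tumour is argued against too, since adrenergic and neuronal genes stood at -0.02 and mitotic genes at -0.63 relative to replicates 1 and 2 (permutation p = 1e-05, the smallest value possible). Its 27 B and T cell markers stood 2.01 higher and 58 macrophage, endothelial and fibroblast markers 0.97 higher (permutation p = 1e-05, again the smallest), but the library was singled out for its B cell markers, so this restates the observation and whether it held more lymphocytes stays open. A difference between individual tumours, or in response to the drug, stays open and was not tested.

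Each 3 against 3 comparison has 10 splits, too few for a share under 0.05. In each, 1 split, the real one, reached the real count of called genes. CBL0137 against vehicle gave 949 genes and at most 2 in any other split, the combination against vehicle 10234 and at most 1, and the combination against CBL0137 8824 and at most 0, all by limma.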

How the results depend on the processing

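Apart from leaving out CBL0137 replicate 3 with combination replicate 1, and panobinostat replicate 3 with combination replicate 2, which were chosen after seeing the data, the alternatives and gene lists were chosen before the data were examined. A count model was not run, since the values are TPM, and without counts the depth limits cannot be stated. Over all alternatives, the 652 results for named genes changed sign 32 times. Of these changes 2 were in results that had been called, Hist2h2be and Hdac8 after panobinostat, at -0.19 and -0.17 under quantile normalization. Hdac8 after the combination, called but outside those 652, also changed sign there, to -0.30. With TMM factors 628 of the 652 kept their direction and call and 18 calls were lost, with quantile normalization 592 and 48, with array weights 633 and 10, and with only the groups compared 567 and 80. The cause was not tested for any change given here, except that fits with fewer libraries have less data.

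For CBL0137 against vehicle the count of 949 became 547 with a pseudocount of 5, 4692 with array weights, 497 without CBL0137 replicate 3 and combination replicate 1, and 324 (without vehicle replicate 3) to 1318 (without combination replicate 2) in leave-one-out fits. For panobinostat 6572 became 4031 (without panobinostat replicate 3) to 7192. The combination against vehicle (10234) ranged from 9256 to 10314 and against CBL0137 (8824) from 7135 to 8938. For the combination against panobinostat 1634 became 3327 with quantile normalization, 477 with only these groups in the fit, 102 without panobinostat replicate 3 and combination replicate 2, and 366 (without panobinostat replicate 1) to 3356 (without combination replicate 3). The interaction count of 0 became 11 with array weights and 0 to 45 (without panobinostat replicate 1) in leave-one-out fits. Lists called were 22, 21, 26, 22, 24 and 12 in the order of the report, and 0 in each with an estimated correlation (lowest adjusted p 0.338, 0.582, 0.480, 0.498, 0.512 and 0.936). In leave-one-out fits they were 21 to 24, 20 to 22, 24 to 26, 21 to 25, 21 to 26 and 9 to 15.

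A replicate block gave 521 genes for CBL0137 and 345 for the combination against panobinostat, and of the 652 gene results 549 kept their direction and call and 102 calls were lost. The numbers do not pair the libraries: libraries with the same number correlated at -0.26 to 0.19, and 1 of 11 was closest to its own number.

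Changes of sign in genes that had not been called were these. Under quantile normalization Mycn stood at -0.012 after CBL0137 and -0.023 after panobinostat, and Cd8a at -0.22 after panobinostat. In leave-one-out fits H1f0 after CBL0137 ranged from -0.024 to 0.28, with -0.011 and -0.007 without CBL0137 replicates 1 and 2, and Th after panobinostat from -0.14 to 0.69. After the combination Mycn was at 0.029 with a pseudocount of 5, 0.03 without vehicle replicate 2, 0.05 without combination replicate 2, alone or with panobinostat replicate 3, and 0.37 without combination replicate 1, alone or with CBL0137 replicate 3, from a lowest value of -0.46. Hdac1 was at -0.17 with TMM factors, -0.002 with quantile normalization, -0.12 with rescaling and -0.056 to 0.14 in leave-one-out fits. Against CBL0137 the combination ranged from -0.68 to 0.36 for Mycn, -0.38 to 0.47 for Th and -0.35 to 0.44 for Cd8a over fits without libraries. Cd8a was at -0.049 with TMM factors, -0.39 with quantile normalization and -0.016 with rescaling.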

Other observations

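The lists in this part were fixed beforehand, and the genes of interferon signalling other than Ifih1 and Ddx58 were chosen after their values were seen. Transcripts of the type I interferon Ifnb1 (chromosome 4, 88522025 to 88522794) were listed at 0 in all 3 vehicle and both panobinostat libraries. They stood at 4.23, 2.49 and 8.65 TPM in CBL0137 replicates 1, 2 and 3 and at 13.7, 25.7 and 3.99 TPM in the combination replicates. The RNA sensors Ifih1 (MDA5) and Ddx58 (RIG-I) rose by 3.71 ± 0.35 and 3.76 ± 0.35 after CBL0137 (log2, SE), by 1.99 and 1.89 after panobinostat, and by 6.13 and 5.76 after the combination. The endosomal RNA receptor Tlr3 rose by 2.05, 1.53 and 4.30 and Tmem173, which encodes STING, by 1.55, 2.33 and 3.57 in the same order. Mb21d1, which encodes the DNA sensor cGAS, was at 0.66 after CBL0137, where it did not pass (limma adjusted p = 0.154), and rose by 0.83 after panobinostat and 2.33 after the combination.

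Clock, hypoxia, germline and red cell genes did not pass as lists against vehicle. Clock genes had a median of -0.30 after CBL0137 with 0 of 17 members called by limma (camera adjusted p = 0.0598). The list passed with TMM factors (0.0426) and without vehicle replicate 3 (0.0348), CBL0137 replicate 3 (0.0242) or combination replicate 2 (0.0357) or 3 (0.0305). After panobinostat 5 clock genes rose and 1 fell (also adjusted over the list alone, camera adjusted p = 0.647). The median was 0.14 (-0.26 quantile-normalized). After the combination 7 rose and 3 fell (also adjusted over the list alone, camera adjusted p = 0.464), with Bhlhe40 and Arntl at 2.44 and 2.03 and Cry1 and Hlf at -0.92 and -2.31. Hypoxia and glycolysis genes had medians of 0.09, 0.36 and 0.47 after CBL0137, panobinostat and the combination (camera adjusted p = 0.533, 0.426 and 0.240). Quantile-normalized medians were -0.01, 0.15 and 0.17. Of 21 members 0, 2 and 8 rose and 0, 0 and 3 fell (also adjusted over the list alone), with P4ha1 at 0.99 after panobinostat and P4ha1 and Pfkfb3 at 1.91 and 2.10 after the combination. Germline genes had medians of -0.24, -0.06 and -0.15 (camera adjusted p = 0.367, 0.647 and 0.604), with Ddx4 at 1.87 and Tdrd1 at -2.66 after the combination (2 of 10 rose and 3 fell, also adjusted over the list alone). Erythroid markers had medians of 0.70, 2.31 and 2.16 (camera adjusted p = 0.514, 0.207 and 0.240), and 3 of 5 rose after the combination (3 adjusted over the list alone). The 4 measured kidney markers had medians of -1.72, -1.03 and -1.50. Vehicle replicates 1, 2 and 3 stood at -1.69, 3.31 and -1.57 from the vehicle mean.

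Several further lists did not pass after CBL0137. Histone genes had a median of -0.16 with 0 of 68 members called by limma (camera adjusted p = 0.180), and the list passed without vehicle replicate 1 (0.0139), CBL0137 replicate 1 (0.0249) or combination replicate 2 (0.00489). Glucocorticoid-responsive genes had a median of 0.17 (camera adjusted p = 0.762), with Lcn2 at 2.56 as the 1 called member of 13 (2 rose and 1 fell adjusted over the list alone). Schwann cell markers had a median of 0.17 (camera adjusted p = 0.393), which was -0.14 under quantile normalization. Neuronal genes had a median of -0.07 and a mean of 0.05, with 0 of 30 called and camera adjusted p = 0.762. Pnmt, which makes adrenaline in the adrenal medulla, stood at 56.9 TPM in combination replicate 2, the library with adrenal cortex transcripts, and at 1.06 and 2.62 TPM in replicates 1 and 3.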
